A study of Mus musculus with 6 samples.

How the data were processed

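Total RNA from flat cultures of mouse forestomach, corpus and antrum epithelium was depleted of ribosomal RNA with a Ribo-Zero kit and sequenced, per the labels' protocols. The authors deposited 1 table of CPM values for the 6 libraries, 2 per region, rounded to 2 decimals. Per the submitters' processing notes, which name tools with no version, order or role, STAR, HTSeq, DESeq2 and edgeR were used with the mouse genome build mm9. Which of these made the CPM table, the gene annotation and whether counting used strand are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. No genome of that build was used here, and no coordinates are given. Genes carry the symbols of the table, of which 14115 of 15450 occur in the GENCODE M21 annotation.

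The table's columns name a region and a number, 1 or 2, which the labels do not tie to their sample IDs, so a column was assigned to its region and not to 1 sample of it. Libraries are called forestomach 1 and so on after these columns. The column named pylorus is the antrum group, whose labels read antrum and pylorus together. Of 15450 rows, 19 whose symbols had turned into dates were left out (at most 0.21% of the listed CPM of a library). Over all rows of the table, 1311 were at 0 in all libraries, and 14121 of the 15431 genes used were above 0.

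The listed CPM values summed to 33.2% to 48.4% of the scale's total in each library, so the deposited scaling counts reads that no listed row holds. The low values lie on even steps, 1 step being 1 read, and these steps gave the library totals: 37.7, 40.4, 36.9, 47.7, 38.7 and 46.9 M reads for forestomach 1, forestomach 2, corpus 1, corpus 2, antrum 1 and antrum 2. Reads on listed rows came to 18.2, 15.9, 14.0, 15.8, 16.7 and 17.5 M. With the inferred step, 100% of values under 200 CPM were whole reads within 0.0051 CPM in each library, against 34.5% to 44.5% with a wrong step. The rounding is coarse against the step, so these reads served for depth and for 1 added alternative only. A level of 3 reads corresponds to 0.063 to 0.081 CPM, which covers counting error only.

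Genes at 1 CPM or more in at least 2 of 6 libraries were tested, 11891 in all. A gene that reaches this level in 1 group only can hardly come out otherwise than higher in that group. Counts of tested list members that all go 1 way carry this limit. A pseudocount of 1 was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) in 1 fit with 3 group means and no block, which leaves 3 residual degrees of freedom and 6.1 prior ones. The 4 comparisons were the mean of corpus and antrum against forestomach, antrum against corpus, and each glandular region against forestomach. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, at 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 23 lists with at least 3 tested members, of 26 lists holding 455 genes. List medians are given relative to the median of all tested genes where so stated. No list call of either comparison held with an estimated correlation. That form of camera rests on the 3 residual degrees of freedom of the fit. Lists with an estimated correlation under 0, such as the neck mucous (-0.0774) and tuft cell (-0.0899) lists in glandular against forestomach, lost their calls too. The loss therefore does not show that correlation between genes undoes a call. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 served for the depth estimate and the figures.

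The lists, the rule for named genes, the tests and all alternatives not given as added were set before the data were examined. The rule took, for glandular against forestomach and for antrum against corpus, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. Unnamed gene models, mitochondrial and Y-linked genes and Xist were left out. Members of the lists were named as examples, those past the threshold with the largest change being preferred.

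The fit was tested on simulated libraries with the real genes' means and 200 genes changed. For glandular against forestomach (11565 genes) it recovered 46 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 7 of the 153 genes called (4.6%) were unchanged ones. For antrum against corpus (11566 genes) it recovered 29 of 100 and 99 of 100, and 16 of the 144 genes called (11.1%) were unchanged ones, a share above the 0.05 threshold and a limit for the 90 genes called there. Each simulation was a single run, with noise independent between libraries and of the same spread in all groups. In the real data the SD of the log2 difference of replicates was 0.57 in forestomach, 0.31 in corpus and 0.37 in antrum. Deviations of corpus and antrum libraries of one number also correlated, at 0.61. The rates are therefore a check of the fit and not error rates of these data. The depth estimate recovered the totals of simulated tables.

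The alternatives were a pseudocount of 0.25 or 5, no filter or a filter of 5 CPM, rescaling by the median ratio, quantile normalization, no intensity trend, only the groups compared in the fit, each library left out in turn, and, for lists, camera with an estimated correlation and fry. Rescaling factors lay between 0.84 and 1.25. A planned block by the labels' IDs was not possible, since columns carry no IDs, and the planned count models were not run, since the rounding keeps the values off exact whole multiples of the step. A block by column number and limma's voom on the implied reads were added after the data were seen, as were 15 gene families chosen by symbol. Groups of 2 libraries allow no test of an outlying library.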

Results

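RNA was sequenced from epithelial cells of 3 regions of the mouse stomach grown as flat (2D) cultures: the forestomach, which in the animal is lined by stratified squamous epithelium, and the corpus and the antrum (antrum and pylorus together), which are lined by columnar epithelium folded into glands. Each region had 2 libraries from wild type mice, 6 libraries in all. The series is about keeping stem cells of the gastric isthmus, the part of the gland below the surface pits, in lasting culture. These libraries profile cultures of the 3 regions side by side. Forestomach cells were grown by a published protocol that differs from the one used for corpus and antrum, so region and culture conditions cannot be separated in any comparison with forestomach. The labels give every region the same pair of sample IDs, 75 and 76, without saying what they stand for, and the deposited columns do not carry them. Nothing in the labels says that the libraries of a region come from separate animals or cultures, so the p-values below measure the spread between these libraries, which may be technical. Levels are in CPM, reads scaled by the size of each library. Fold changes are log2 differences of CPM + 1, a scale that understates the change of genes with low levels. Whole-read steps in the low values put the total behind each library at about 36.9 to 47.7 M reads, of which about 14.0 to 18.2 M fell on listed genes, and 3 reads were worth 0.063 to 0.081 CPM. A value of 0 is given below as listed at 0, because genes used by every cell, such as the cholesterol synthesis genes Hmgcs1 and Msmo1, were also listed at 0 in all 6 libraries.

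Of 15431 genes used, 11891 reached 1 CPM in at least 2 libraries and were tested. Corpus and antrum libraries were close to each other and far from forestomach. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.968 to 0.982 between corpus and antrum libraries and 0.663 to 0.704 between these and forestomach libraries. Libraries of one region had r = 0.959 in forestomach, 0.986 in corpus and 0.980 in antrum. The forestomach libraries differed most from each other, with 1488 genes (12.5%) more than 2-fold apart, against 121 (1.0%) in corpus and 161 (1.4%) in antrum. The proliferation gene Mki67, for example, stood at 239 and 74.1 CPM in the 2 forestomach libraries. The first principal component, which carried 84.8% of the variance, separated forestomach from the glandular libraries.

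The comparison of glandular (corpus and antrum) with forestomach cultures asked how the columnar and the squamous epithelium differ when grown in culture. Forestomach cultures had high levels of squamous keratins, and glandular cultures of columnar keratins and of gastric secreted products. Krt14 and Krt5, the keratins of squamous basal cells, stood at 7141 ± 121 and 3164 ± 779 CPM in forestomach (SD, n = 2) and at 1.35 ± 0.296 and 0.512 ± 0.342 CPM in the glandular cultures (SD, n = 4). Krt8, a keratin of columnar cells, and Cldn18, a tight junction protein of the stomach, stood at 1260.1 ± 384 and 1089.6 ± 96 CPM in the glandular cultures and at 0.545 ± 0.0636 and 0.025 ± 0.0071 CPM in forestomach. The pepsinogen gene Pgc reached 886 ± 649 CPM and the pit mucin Muc5ac 322 ± 169 CPM in the glandular cultures, against 0.025 ± 0.0071 and 0.075 ± 0.0636 CPM in forestomach. In the limma fit 5683 of 11891 genes differed at an adjusted p under 0.05, 2508 higher and 3175 lower in the glandular cultures. Of these, 3824 differed more than 2-fold, 1847 higher and 1977 lower.

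The named genes higher in the glandular cultures were Apob, Cldn18, Krt8, Pgc, Gkn2, Anxa10, Cybrd1, Gkn1, Tspan8, Ctse, Muc5ac and Sepp1. Apob, the structural protein of lipoprotein particles, had the largest log2 fold change of these, 10.18 (SE 0.33, adjusted p = 4.94e-08), at 1316 ± 433 CPM (SD, n = 4) against 0.085 ± 0.0495 CPM (SD, n = 2). Gkn2, a secreted product of pit cells, was listed at 0 in both forestomach libraries and stood at 1174, 1660, 375 and 229 CPM in corpus 1, corpus 2, antrum 1 and antrum 2. The tetraspanin Tspan8 and the aspartic protease Ctse were also listed at 0 in both forestomach libraries, with means of 283 ± 33.2 and 262 ± 53.2 CPM in the glandular cultures. Cybrd1, an iron reductase, had a log2 fold change of 8.97 (SE 0.22, adjusted p = 1.94e-08). The named genes lower in the glandular cultures were Krt14, Krt5, Krt17, Krt6a, Dsc3, Hspb1, Dsg3, Htra1, Krt16, Col17a1, Pkp1 and Wnt4. Krt14 had the largest fall of these, a log2 fold change of -11.58 (SE 0.22, adjusted p = 1.61e-08). The desmosomal genes Dsc3 (-8.96, SE 0.27, adjusted p = 3.47e-08), Dsg3 (-8.41, SE 0.24, adjusted p = 3.21e-08) and Pkp1 (-7.94, SE 0.37, adjusted p = 3.19e-07) and the hemidesmosomal collagen Col17a1 (-8.16, SE 0.23, adjusted p = 2.95e-08) were lower as well. So was the small heat shock protein gene Hspb1 (-8.76, SE 0.21, adjusted p = 1.94e-08). All 24 named genes had no overlap between the libraries of the groups. Krt6a belongs to a family of close copies whose reads the authors' counting could have split.

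**Figure D1:**
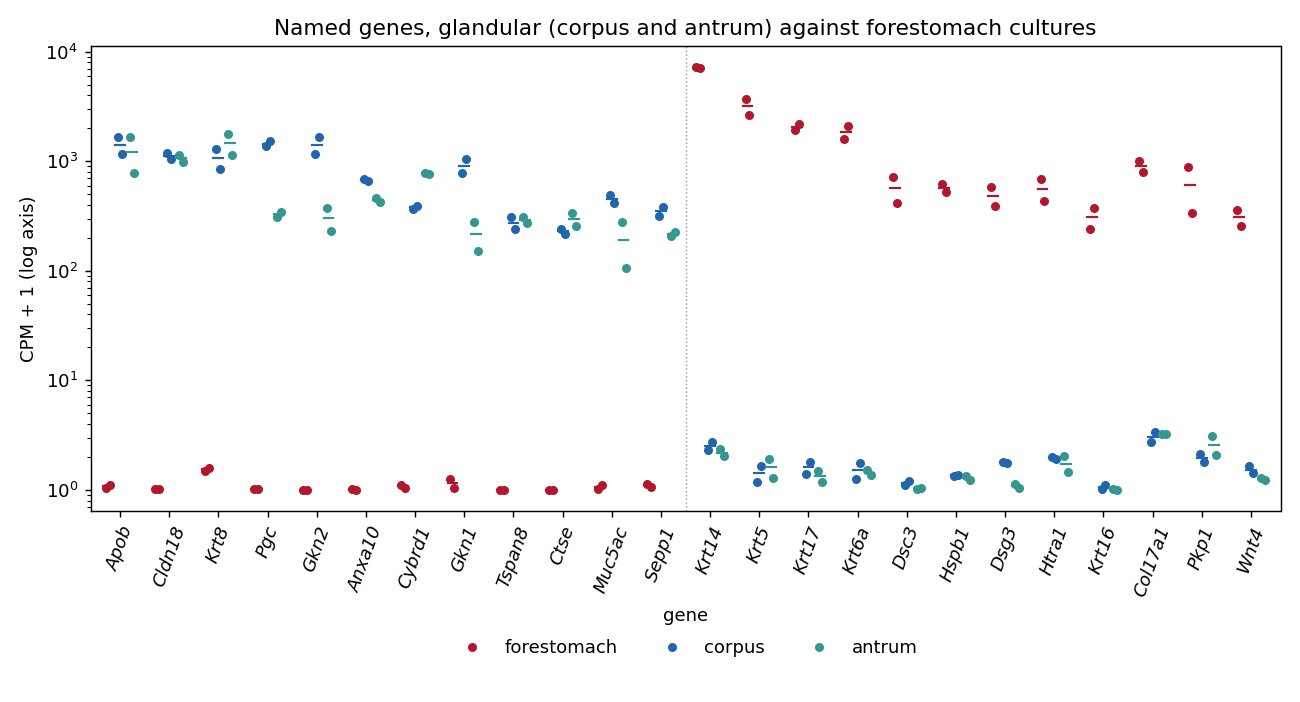
CPM + 1 on a log axis for the 24 genes named for glandular against forestomach, with 1 dot per library coloured by region, a bar at each group mean, and a dotted line between genes higher and genes lower in the glandular cultures. Krt14 stands at 7141 CPM on average in forestomach and at 1.35 CPM in the glandular cultures, while Apob stands at 0.085 and 1316 CPM.

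Genes of squamous cells were lower in the glandular cultures. Of 23 tested squamous basal identity genes, 21 were lower, 21 adjusted over the list alone, and none was higher. The list's median log2 fold change was -3.94 relative to the median of all genes (camera, adjusted p = 2.45e-13, and adjusted p = 0.121 with an estimated correlation). Trp63, the transcription factor that sets up squamous basal cells, stood at 159 ± 29.8 CPM in forestomach (SD, n = 2) and at 0.0125 ± 0.015 CPM in the glandular cultures (SD, n = 4). The members that did not pass were Gpc1, at 16.1 ± 0.856 and 13.9 ± 3.15 CPM, and Pax9, at 3.97 ± 2.22 and 2.22 ± 1.23 CPM. Of 22 tested genes of squamous suprabasal differentiation 14 were lower, 15 adjusted over the list alone, 4 were higher and 4 did not pass (median -2.53 relative to all genes, adjusted p = 0.000418, and adjusted p = 0.149 with an estimated correlation). Krt13 fell from 76.6 ± 20.4 to 0.193 ± 0.128 CPM. Higher in the glandular cultures were, among others, Sprr2a1 (1.91, SE 0.21, adjusted p = 8.12e-05), the involucrin gene Ivl (1.36, SE 0.35, adjusted p = 0.0108) and the transcription factor Grhl3 (1.51, SE 0.24, adjusted p = 0.000834), which all stood under 12 CPM on average. Sprr2a1 has close copies.

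Genes of glandular cell types were higher in the glandular cultures. Of 28 tested columnar identity genes 26 were higher, 27 adjusted over the list alone, and none was lower (median 5.07 relative to all genes, adjusted p = 3.39e-20, and adjusted p = 0.121 with an estimated correlation). The cell surface mucin Muc1 stood at 165 ± 31.2 CPM (SD, n = 4) against 0.01 ± 0.0141 CPM (SD, n = 2), while Ehf (75.7 ± 30.2 against 41.6 ± 32.2 CPM) did not pass. All 12 tested pit mucous cell genes were higher (median 7.33, adjusted p = 5.64e-13) and all 11 neck and deep gland mucous cell genes were higher (median 4.13, adjusted p = 7.47e-10), each with an adjusted p = 0.121 with an estimated correlation. The pit list member Tff1 had only about 2 or 3 reads in each glandular library and was not tested. Muc6, the gland mucin, stood at 69.5 ± 20.2 against 0.05 ± 0.0283 CPM. All 6 tested chief cell genes were higher (median 3.59, adjusted p = 8.38e-06), as were 7 of 8 tested parietal cell genes, 8 adjusted over the list alone (median 2.11, adjusted p = 5.36e-05), and all 3 tested tuft cell genes (median 3.35, adjusted p = 0.00408), again each with an adjusted p = 0.121 with an estimated correlation. Atp4a, the catalytic subunit of the acid pump that marks parietal cells, stood at 0.725 ± 0.264 CPM in the glandular cultures and did not reach the level needed for testing. The parietal list members that rose included Car2 (6.58, SE 0.28, adjusted p = 1.66e-07), a carbonic anhydrase, and the metabolic regulator Ppargc1a (4.54, SE 0.25, adjusted p = 8.94e-07). The tuft cell list rested on Avil, Ptgs1 and Dclk1. Its other members, such as Alox5ap at 0.055 ± 0.0656 CPM, were not tested. Counts within these 6 lists were the same adjusted over the list alone except where given. Many members entered the test through the glandular libraries only and could hardly come out lower. Of the tested genes, 3 of 12 pit, 2 of 11 neck, 1 of 6 chief, 5 of 8 parietal and 0 of 3 tuft cell genes reached 1 CPM in both forestomach libraries. The limit is therefore weakest for the parietal list.

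Stem cell and pathway lists were called higher in the glandular cultures, most of them with members lower as well. Some lists share genes. Of the 20 stem and progenitor markers 10 are also in another list, as are 4 of the 16 Wnt target genes. Their calls are therefore not separate findings in either comparison. Of 17 tested gastric stem and progenitor markers 8 were higher, 3 lower and 6 did not pass, with 9 higher and 3 lower adjusted over the list alone (median 0.62 relative to all genes, adjusted p = 0.00512, and adjusted p = 0.122 with an estimated correlation). Prom1 (7.85, SE 0.22, adjusted p = 2.95e-08) was higher, and Cd44 (-1.25, SE 0.26, adjusted p = 0.00388) and Ly6a (-1.66, SE 0.31, adjusted p = 0.00217) were lower. The Wnt-responsive receptor gene Lgr5 was listed at 0 in both forestomach libraries and stood at 14.1, 15.8, 9.55 and 11.9 CPM in corpus 1, corpus 2, antrum 1 and antrum 2. Of 12 Wnt target genes 9 were higher, 10 adjusted over the list alone, and none was lower (median 1.44, adjusted p = 0.000254, and adjusted p = 0.121 with an estimated correlation), with Axin2 at 12.2 ± 5.19 against 2.18 ± 1.64 CPM. Of 9 BMP and TGF-beta target genes 7 were higher and 2 lower (median 1.51, adjusted p = 0.0179, and adjusted p = 0.26 with an estimated correlation). Id1 rose (3.82, SE 0.28, adjusted p = 4.67e-06) and Tgfbi fell (-2.18, SE 0.17, adjusted p = 6.58e-06). Of 16 YAP and regeneration-associated genes 9 were higher, 4 lower and 3 did not pass (median 1.61, adjusted p = 0.0103, and adjusted p = 0.224 with an estimated correlation). The secreted chaperone gene Clu stood at 2977 ± 711 against 14.6 ± 5.16 CPM and Msln at 1052 ± 374 against 12 ± 6.37 CPM, whereas Anxa1 fell from 1664 ± 196 to 279 ± 135 CPM. The BMP and YAP counts were the same adjusted over the list alone.

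Regional transcription factors differed between the cultures as well. Of 6 tested antral and pyloric patterning genes 5 were higher and Gata3 was lower in the glandular cultures (median 2.79 relative to all genes, adjusted p = 0.00415, and adjusted p = 0.121 with an estimated correlation). Of 7 corpus patterning genes 2 were higher and 5 lower (median -1.64, adjusted p = 0.231, and adjusted p = 0.559 with an estimated correlation). Irx1 stood at 35.8 ± 19.9 CPM in forestomach (SD, n = 2) and at 0.005 ± 0.01 CPM in the glandular cultures (SD, n = 4), while Sox21 rose (1.42, SE 0.26, adjusted p = 0.0018). All 4 tested Hox genes were lower (median -2.51, adjusted p = 0.00169, and adjusted p = 0.121 with an estimated correlation). Of the 24 Hox genes 4 were above 1 CPM in both forestomach libraries and 0 in all glandular ones, so tested ones could hardly come out higher. Of 7 tested intestinal epithelium genes 6 were higher and 1, Ada, was lower (median 1.79, adjusted p = 0.00461, and adjusted p = 0.121 with an estimated correlation). Villin (Vil1) was listed at 0 in both forestomach libraries and averaged 112 ± 55.4 CPM in the glandular cultures. The counts of these 4 lists were the same adjusted over the list alone.

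Proliferation and cholesterol synthesis genes were lower in the glandular cultures. Of 30 proliferation genes 27 were lower, 27 adjusted over the list alone, and none was higher (median -1.21 relative to all genes, adjusted p = 9.69e-08, and adjusted p = 0.224 with an estimated correlation). The ribonucleotide reductase gene Rrm2 fell from 179 ± 12 CPM (SD, n = 2) to 28.1 ± 9.5 CPM (SD, n = 4), whereas Mki67, at 157 ± 117 and 182 ± 70.8 CPM, did not pass. Of 16 cholesterol biosynthesis genes 12 were lower, 13 adjusted over the list alone (median -1.01, adjusted p = 0.000157, and adjusted p = 0.289 with an estimated correlation), among them Idi1 (-2.38, SE 0.22, adjusted p = 2.15e-05). Of 12 interferon response genes 10 were higher (median 1.26, adjusted p = 0.000132, and adjusted p = 0.122 with an estimated correlation), with Oas1a, for example, at 5.44 ± 1.46 against 0.835 ± 0.163 CPM. Of 14 endoplasmic reticulum stress genes 7 were higher and 7 did not pass (median 0.97, adjusted p = 0.00369, and adjusted p = 0.424 with an estimated correlation), with Herpud1 at 112 ± 19 against 28.7 ± 7.86 CPM. The 14 immediate early and heat shock genes went both ways. Among them 3 were higher, such as Egr1 (1.52, SE 0.22, adjusted p = 0.000451), 6 were lower, such as Hspb1, and 5 did not pass. They did not pass as a list (median -0.39, adjusted p = 0.307, and adjusted p = 0.559 with an estimated correlation). The counts of these last 3 lists were the same adjusted over the list alone.

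Markers of other cell types that a culture can hold were measured too. Of 14 tested fibroblast and feeder cell genes 13 were higher and 1, Acta2, was lower in the glandular cultures (median 2.77 relative to all genes, adjusted p = 1.32e-06, and adjusted p = 0.211 with an estimated correlation). Col1a1, for example, averaged 14.4 ± 4.26 CPM (SD, n = 4) against 0.025 ± 0.0354 CPM (SD, n = 2), and Vim 8.83 ± 2.87 against 0.065 ± 0.0919 CPM. Of 3 tested endothelial genes 2 were higher and 1, Egfl7, was lower (median 1.05, adjusted p = 0.516, and adjusted p = 0.559 with an estimated correlation). Both counts were the same adjusted over the list alone. The immune cell, class II antigen presentation and enteroendocrine lists had 2 tested members each, too few for a list test. Cd68 fell from 42.2 ± 3.74 to 4.31 ± 0.558 CPM and Cd14 rose from 2.5 ± 1.18 to 8.29 ± 3.75 CPM. The class II genes H2-Ab1 (0.055 ± 0.0493 against 3.91 ± 0.396 CPM) and H2-Eb1 (0.0125 ± 0.015 against 1.31 ± 0.247 CPM) were lower. Insm1 and Isl1 were listed at 0 in forestomach and averaged 2.66 ± 1.01 and 3.63 ± 4.23 CPM in the glandular cultures.

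**Figure D2:**
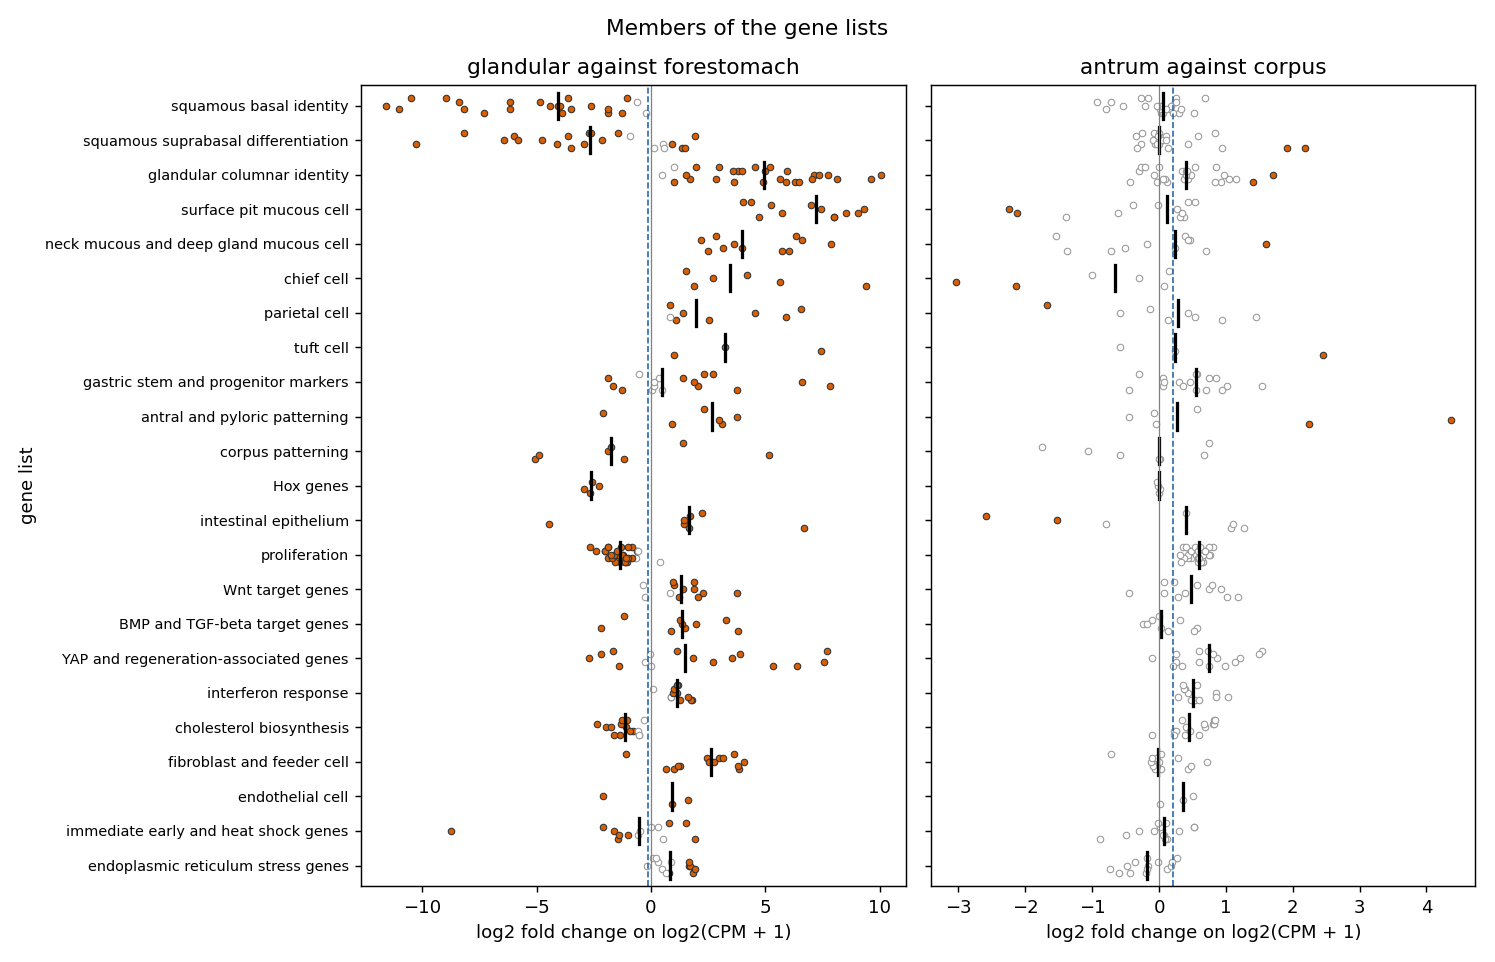
Log2 fold change of each tested gene by list, with filled orange points for genes at an adjusted p under 0.05, a black bar at the list median, a blue dashed line at the median of all tested genes and a grey line at 0. In glandular against forestomach the columnar identity list lies above and the squamous basal list below the median of all genes.

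Across all genes the median log2 fold change was -0.13, and rescaling the libraries to a common median ratio moved it to 0.02, with 6376 genes differing and 3364 of them higher. Without forestomach 1 the count was 5785, of which 3490 were higher, and without forestomach 2 it was 5627, of which 2130 were higher.

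The comparison of antrum with corpus cultures, both grown by the same protocol, asked what sets the glandular regions apart in culture. Antrum cultures were higher for the antral transcription factors Nkx6-3 and Pdx1 and for the sodium-proton exchanger gene Slc9a3, and lower for Gif (gastric intrinsic factor), Pgc and the gastrokines Gkn1 and Gkn2. Nkx6-3 stood at 35.4 ± 9.44 CPM in antrum against 0.95 ± 1.26 CPM in corpus (SD, n = 2 each), a log2 fold change of 4.37 (SE 0.42, adjusted p = 0.00248), and Pdx1 at 17.6 ± 0.608 against 2.96 ± 0.757 CPM (2.24, SE 0.24, adjusted p = 0.00449). Pgc, the most abundant in corpus of the named genes lower in antrum, stood at 327 ± 27.4 against 1445 ± 101 CPM (-2.14, SE 0.26, adjusted p = 0.00685). In the limma fit 90 of 11891 genes differed at an adjusted p under 0.05, 66 higher and 24 lower in antrum, all by more than 2-fold, and 943 did so at an unadjusted p under 0.05. The spread in this fit is shared with forestomach, whose libraries differed most from each other. With only corpus and antrum in the fit, 1892 genes had an unadjusted p under 0.05 and 26 were called. Genes not called here are therefore not shown to be alike in the glandular regions.

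The other named genes higher in antrum were Prap1, Clca3, Ildr1, Cdhr2, Tgfb3, Cdo1, Odz1, Ceacam1 and Adamtsl4. Slc9a3 stood at 37.8 ± 5.59 against 1.02 ± 0.969 CPM (SD, n = 2 each, log2 fold change 4.34, SE 0.33, adjusted p = 0.00066) and Prap1, a secreted protein gene, at 19.7 ± 2.31 against 0.11 ± 0.0707 CPM (4.22, SE 0.22, adjusted p = 0.000113). Cdhr2, a microvillus cadherin, stood at 51.3 ± 14.9 against 5.08 ± 1.48 CPM (3.10, SE 0.30, adjusted p = 0.00248), and Tgfb3, a TGF-beta ligand, at 30.2 ± 8.07 against 4.77 ± 0.962 CPM (2.42, SE 0.27, adjusted p = 0.00524). The named genes lower in antrum were Gif, Anpep, Fam3c, Gkn2, Pgc, Gkn1, Ugt2b35 and Ugt2b34, which were all that passed the rule. Gif stood at 17.5 ± 9.03 against 150.4 ± 72.2 CPM (-3.04, SE 0.42, adjusted p = 0.015) and Anpep, an aminopeptidase, at 6.01 ± 1.97 against 48.1 ± 5.06 CPM (-2.83, SE 0.31, adjusted p = 0.00466). The Ugt2b genes have close copies. The calls of Clca3 and Cdhr2 held under all 17 alternatives, each library left out in turn included. Those of Prap1 and Ildr1 held under the 15 in which they could be tested. These 15 do not include the fits without antrum 1 or without antrum 2, where both genes fell below the filter. Without corpus 2 no gene was called lower, and Gkn1, Gkn2, Pgc, Fam3c, Adamtsl4 and Ugt2b34 lost their calls without any 1 of the 4 glandular libraries. Ugt2b35 kept its call in only 3 of 17 alternatives and lost it, for example, after quantile normalization, without either forestomach library and after rescaling, where its log2 fold change went from -2.06 (SE 0.36) to -2.27 (SE 0.39, adjusted p = 0.0641).

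**Figure D3:**
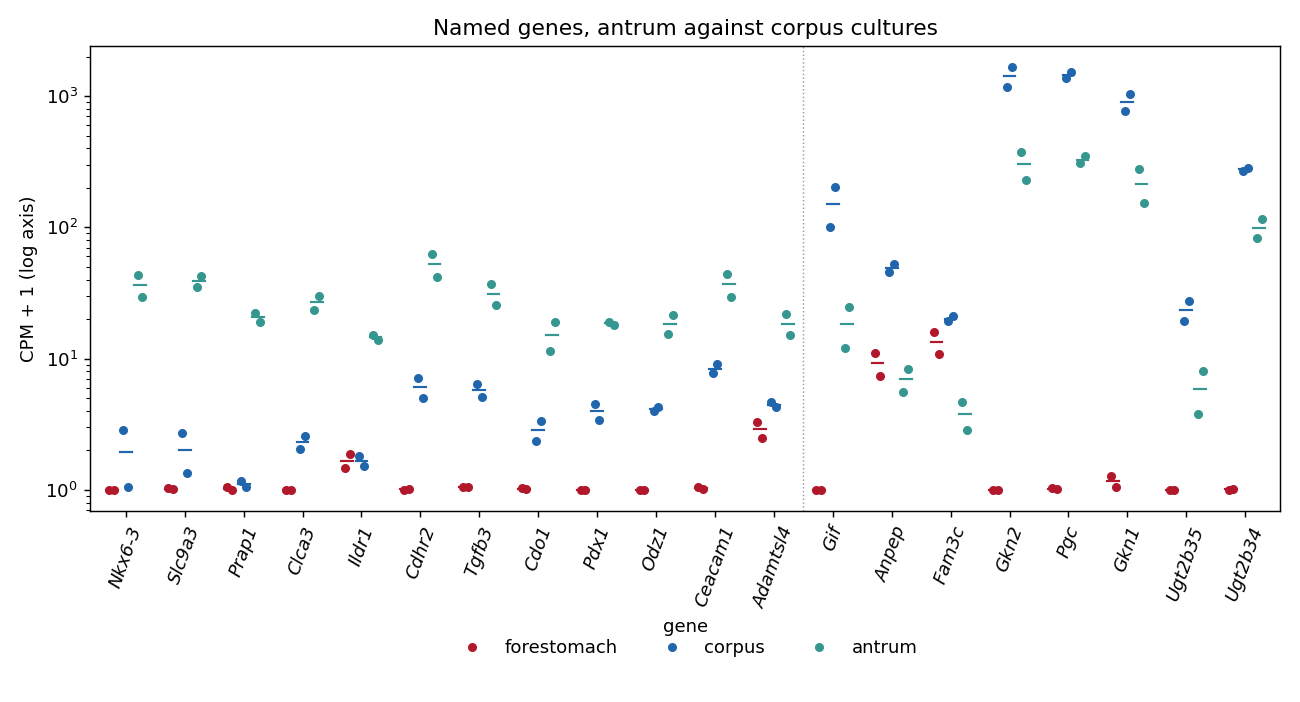
CPM + 1 on a log axis for the 20 genes named for antrum against corpus, drawn as in the plot for glandular against forestomach, with the dotted line between genes higher and genes lower in antrum. Prap1 stands at 21.3 and 18.1 CPM in antrum and at 0.16 and 0.06 CPM in corpus.

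Few genes of the cell type lists were called between antrum and corpus. Of 6 tested chief cell genes 2, Gif and Pgc, were lower, 3 adjusted over the list alone (median -0.86 relative to all genes, adjusted p = 6.75e-10, and adjusted p = 0.377 with an estimated correlation). Of 12 pit mucous cell genes 2, Gkn1 and Gkn2, were lower, 3 adjusted over the list alone (adjusted p = 6.77e-05, and adjusted p = 0.381 with an estimated correlation). The pit list's median was -0.09 relative to all genes, and Muc5ac, at 191 ± 122 CPM in antrum and 452 ± 50.3 CPM in corpus (SD, n = 2 each), did not pass. Of 11 neck and deep gland mucous cell genes 1, Gkn3, was higher (416 ± 36.2 against 136 ± 2.4 CPM, adjusted p = 0.0256), and adjusted over the list alone 1 was higher and 3 lower. The neck list was called lower (adjusted p = 0.0294, and adjusted p = 0.377 with an estimated correlation) with a median of 0.02 relative to all genes, and lost the call after rescaling (adjusted p = 0.134). Of 28 columnar identity genes 2, Onecut2 and Cldn3, were higher, 6 adjusted over the list alone (adjusted p = 0.0351, adjusted p = 0.527 with an estimated correlation and adjusted p = 0.0583 after rescaling). Cldn3 lost its call after rescaling, with a log2 fold change of 1.41 (SE 0.25) before and 1.32 (SE 0.24, adjusted p = 0.0822) after. Of 8 parietal cell genes 1, Esrrg, was lower, with 1 higher and 1 lower adjusted over the list alone (list test adjusted p = 0.298), and of 3 tuft cell genes 1, Dclk1, was higher, at 6.34 ± 0.863 against 0.33 ± 0.0283 CPM (list test adjusted p = 0.314).

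Regional and intestinal lists held few called genes. Of 6 antral and pyloric patterning genes 2, Nkx6-3 and Pdx1, were higher, 2 adjusted over the list alone (list test adjusted p = 0.0563, adjusted p = 0.381 with an estimated correlation and adjusted p = 0.039 after rescaling). Lgr5, a member of this list, was not called and stood at 9.55 and 11.9 CPM in antrum and at 14.1 and 15.8 CPM in corpus. None of 7 corpus patterning genes passed over all genes and 2 were lower adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.424 with an estimated correlation). That list's median was -0.21 relative to all genes, and it lost the call after rescaling (adjusted p = 0.138). Of 7 intestinal epithelium genes 2, Apoa1 (0.395 ± 0.134 against 7.48 ± 2.06 CPM) and Reg3g (0.585 ± 0.0212 against 3.76 ± 1.87 CPM), were lower (SD, n = 2 each), and 3 were higher and 3 lower adjusted over the list alone (list test adjusted p = 0.0626). Reg3g lost its call after rescaling, with a log2 fold change of -1.53 (SE 0.27) before and -1.69 (SE 0.31, adjusted p = 0.0782) after. Isl1, an enteroendocrine list member and transcription factor of endocrine and other lineages, stood at 6.32 and 8.16 CPM in corpus and at 0.03 and 0.02 CPM in antrum (adjusted p = 0.000557). None of 4 Hox genes (list test adjusted p = 0.178), 14 fibroblast and feeder genes (adjusted p = 0.0626) or 3 endothelial genes (adjusted p = 0.666) was called, over all genes or adjusted over the list alone. Of the 2 tested genes each of the immune and class II lists, none was called.

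Several lists were called without a called member. Members were tested with a spread shared with the forestomach libraries, so their not passing does not show that the regions are alike. The 30 proliferation genes were all above 0, with a median of 0.38 relative to all genes (higher, adjusted p = 2.62e-07, and adjusted p = 0.407 with an estimated correlation), but none passed, whether over all genes or over the list alone. Mki67, for example, stood at 226 ± 86 CPM in antrum and 139 ± 11.3 CPM in corpus (SD, n = 2 each). The antrum libraries differed on this list as well, with a median log2 ratio of antrum 1 to antrum 2 of -0.36, against 0.15 for all genes. None of 16 YAP and regeneration-associated genes passed over all genes and 4 were higher adjusted over the list alone (median 0.53, higher, adjusted p = 2.91e-05, and adjusted p = 0.377 with an estimated correlation), with Il33 at 47.6 ± 6.13 against 16.2 ± 2.33 CPM. Interferon response genes were called higher (12 genes, 2 passing adjusted over the list alone, adjusted p = 0.000553, and adjusted p = 0.377 with an estimated correlation), as were cholesterol biosynthesis genes (16 genes, none over the list alone, adjusted p = 0.00164, and adjusted p = 0.428 with an estimated correlation). Gastric stem and progenitor markers were called higher (17 genes, 2 over the list alone, adjusted p = 0.0161, and adjusted p = 0.377 with an estimated correlation), as were Wnt target genes (12 genes, 2 over the list alone, adjusted p = 0.0398, and adjusted p = 0.409 with an estimated correlation). Endoplasmic reticulum stress genes were called lower with no member passing, over all genes or over the list alone (14 genes, adjusted p = 0.000553, and adjusted p = 0.428 with an estimated correlation). The same held for the squamous basal genes (23 genes, adjusted p = 0.00516, and adjusted p = 0.428 with an estimated correlation) and the immediate early and heat shock genes (14 genes, adjusted p = 0.0398, and adjusted p = 0.424 with an estimated correlation). The latter pair had medians of 0.06 and 0.07, above 0 and below that of all genes, and lost the call after rescaling (adjusted p = 0.0759 and 0.0872). Of 22 squamous suprabasal genes 2, Krt4 and Tgm1, were higher, 2 adjusted over the list alone (list test adjusted p = 0.556), of which Krt4 lost its call after rescaling (log2 fold change 1.915, SE 0.306, before and 1.796, SE 0.315, adjusted p = 0.0664, after), and none of 9 BMP and TGF-beta target genes was in either (adjusted p = 0.371). Among lists that did not pass, the test pointed lower while the median relative to all genes was above 0 for the intestinal (0.20) and parietal (0.08) lists.

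The median log2 fold change of all genes was 0.21, and rescaling moved it to 0.006, with 66 genes called, 41 higher and 25 lower (62.1% higher, against 73.3% as deposited), while quantile normalization called 77, 45 higher and 32 lower. Without corpus 1 the count was 23, without corpus 2 or without antrum 1 it was 10, without antrum 2 it was 18, and it lay between 26 and 54 with no filter on low values, no intensity trend, voom on implied reads or only the groups compared in the fit. If the numbers of the columns follow the shared IDs, antrum and corpus libraries of one number belong together. An added block by column number gave 33 genes over all regions and 14 within corpus and antrum. A block uses up residual degrees of freedom, so a call lost under it does not mean a weaker difference. Within corpus and antrum the calls of Nkx6-3, Prap1, Clca3, Ildr1, Cdhr2, Tgfb3, Cdo1 and Gif were kept, and those of the other 12 named genes were lost, Pdx1, Slc9a3, Pgc, Gkn1, Gkn2 and Anpep among them. Over all regions the calls of Ceacam1, Gkn1, Gkn2, Ugt2b34 and Ugt2b35 were lost. Of the lists, 14 were called with the block within corpus and antrum too, but the Wnt target list lost its call (adjusted p = 0.0605) and the fibroblast and feeder list gained one (lower, adjusted p = 0.0422).

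Each glandular region was also set against forestomach. In corpus 5178 of 11891 genes differed from forestomach at an adjusted p under 0.05 (limma), 2032 higher and 3146 lower (39.2% higher). In antrum 4630 differed, 2407 higher and 2223 lower (52% higher). In both regions Krt14 was near 1 CPM, at 1.52 ± 0.311 CPM in corpus and 1.18 ± 0.226 CPM in antrum (SD, n = 2 each), against 7141 ± 121 CPM in forestomach, and Cldn18 stood at 1115 ± 104 and 1064 ± 119 CPM, against 0.025 ± 0.0071 CPM. The median of all genes was -0.23 in corpus and -0.03 in antrum, and after rescaling it was 0.03 and 0.01. After rescaling 5645 genes differed in corpus, 2979 higher and 2666 lower (52.8% higher), and 5479 in antrum, 2941 higher and 2538 lower. Without forestomach 1 the share of higher genes was 54.7% in corpus and 68.3% in antrum, and without forestomach 2 it was 32.3% and 45.6%, so the balance of higher and lower genes changes with single forestomach libraries. Without corpus 2 the corpus count was 3005, and without antrum 1 or antrum 2 the antrum count was 3007 or 3008. The 2 comparisons share the forestomach libraries, and their overlap was not analysed here.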

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

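The block by column number and voom on implied reads were added after the data were seen. For glandular against forestomach the count of 5683 genes stayed within 1.5 times under every alternative run, from 4299 without corpus 2 to 6376 after rescaling. The 90 genes of antrum against corpus became 54 with no filter on low values, 48 with no intensity trend, 26 with only the groups compared and 54 with voom, where 46, 48, 23 and 49 of the 90 were kept. With 1 library left out they ranged from 10 (without corpus 2 or antrum 1) to 76, with 23 without corpus 1 and 18 without antrum 2. Fewer libraries leave 1 in a group, which is then assumed to vary like the others. Corpus against forestomach then ranged from 3005 (without corpus 2) to 5505, and antrum against forestomach from 3007 (without antrum 1; 3008 without antrum 2) to 5198. The labels do not say whether column numbers pair the libraries. Deviations from the group mean correlated at -0.06, -0.11 and 0.61 across genes for forestomach with corpus, forestomach with antrum and corpus with antrum, so corpus and antrum libraries of one number deviated together and forestomach ones did not. The spliceosomal RNAs U1, U2, U4 and U6 were higher in library 2 of all 3 regions, so whether the numbers mark a batch or an animal stays open. A replicate block over all regions gave 33 genes for antrum against corpus, and a block within corpus and antrum 14, with fewer residual degrees of freedom in each. Lists past the threshold went from 20 (glandular against forestomach) and 14 (antrum against corpus) to 0 in each with an estimated correlation. With fry, which tests a list against 0, 14 lists were higher and 6 lower in glandular against forestomach. There the endoplasmic reticulum stress list lost its call (fry adjusted p = 0.0513). The immediate early and heat shock list gained one (lower, fry adjusted p = 0.0042). In antrum against corpus fry called 0 lists. It turned the squamous basal (adjusted p = 0.967), neck mucous (adjusted p = 0.95) and immediate early and heat shock lists (adjusted p = 0.967) to the other direction there. Levels under 3 reads (0.063 to 0.081 CPM) cannot be told from 0 at this depth. For the 253 named genes and called list members of glandular against forestomach, 3829 of 3909 values kept their call, 80 lost it and 0 reversed. For the 30 of antrum against corpus, 322 of 487 kept it, 165 lost it and 0 reversed. The block by the labels' IDs and the count models were not run, and a fit of only the groups compared does not apply to glandular against forestomach, which uses all 6 libraries. Where not given above, the cause of a lost call was not tested.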

Other observations

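The gene families and tests below were chosen after the results were seen. Genes of 15 families were compared between glandular and forestomach cultures (limma, adjusted over all genes), and not every family passed as a list. Cytosolic ribosomal protein genes had the smallest list p, with 35 of 81 lower and none higher (camera adjusted p = 1.93e-06, and adjusted p = 0.616 with an estimated correlation). Of 36 proteasome subunit genes 27 were lower and none higher (adjusted p = 2.65e-05, and adjusted p = 0.386 with an estimated correlation). Of 83 genes with symbols like those of respiratory chain and ATP synthase subunits 23 were lower and none higher (adjusted p = 0.00185, and adjusted p = 0.616 with an estimated correlation). The symbols also took in genes that are not subunits, such as Ndufaf2 and Cox4nb, both among the 23. Of these 83 genes 14 were lower adjusted over the list alone, and after rescaling 17 were lower and 1 higher. All 6 tested Wnt ligand genes were lower in the glandular cultures, 6 after rescaling too (camera adjusted p = 8.26e-05, and adjusted p = 0.341 with an estimated correlation). Of these, Wnt3a, Wnt4, Wnt9a and Wnt10a stayed under 1 CPM in the glandular cultures. They entered the test through forestomach only and could hardly come out higher, so the count and the list test carry this limit. Wnt4 stood at 0.395 ± 0.188 CPM (SD, n = 4) against 308 ± 71.7 CPM (SD, n = 2), Wnt10a at 0.307 ± 0.269 against 87.2 ± 6.64 CPM and Wnt7b at 1.59 ± 1.41 against 22.0 ± 6.37 CPM. Of 9 claudin genes 7 were higher and 2 lower (list higher, adjusted p = 0.00185). Cldn2, a pore-forming claudin, stood at 102 ± 6.91 against 0.015 ± 0.0212 CPM, and Cldn1 at 0.647 ± 0.19 against 38.9 ± 14.1 CPM. Of 11 desmosomal genes 4 were higher and 7 lower (list test not passed, adjusted p = 0.17), and of 6 connexin genes 1 was higher and 3 lower (not passed, adjusted p = 0.389), with Gja1 at 1.6 ± 0.406 against 164 ± 7.86 CPM. Of 16 genes of the Slc4, Slc9 and Slc26 ion transporter families 10 were higher and 2 lower (list higher, adjusted p = 0.000208), with Slc4a4 at 255 ± 52.4 against 0.075 ± 0.0778 CPM. Of 44 genes of UDP-glucuronosyltransferases, cytochromes P450 and glutathione transferases 25 were higher and 7 lower (list higher, adjusted p = 7.82e-05). The claudin, ion transporter and enzyme lists each had an adjusted p = 0.341 with an estimated correlation. In antrum against corpus the growth factor receptor gene Fgfr2 was higher, at 12.6 ± 1.35 against 2.63 ± 0.346 CPM (SD, n = 2 each, limma adjusted p = 0.0238).

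Fibroblast transcripts were higher in the glandular cultures, at 13 of 14 tested genes, with Col1a1, Col3a1 and Col1a2 averaging 14.4, 16.3 and 13.7 CPM. Rescaling moved the median log2 fold change of all genes only from -0.13 to 0.02, against a list median of 2.64, and 13 of the 14 stayed higher. Changes of that size argue against the authors' scaling. A small share of fibroblasts or feeder cells predicts that these genes move together between libraries of one region, and their median log2 ratio of corpus 1 to corpus 2, 0.85, lay at percentile 100 of 10000 random lists of like expression, against 0.17 for all genes. Of the other 22 lists 1, chief cell genes, also lay in the outer 2.5% at either end in that pair. In the antrum pair the fibroblast genes did not stand out: their median log2 ratio was 0.19, at percentile 67.66, against 0.15 for all genes, and 4 of the other 22 lists, the proliferation, stem and progenitor, suprabasal and pit mucous ones, lay in the outer 2.5% at either end. None of the list's genes is in another list, and 2 of the 20 were above 1 CPM in both forestomach libraries and 11 in all glandular ones. The corpus value is what such cells would give, but genes switched on together within epithelial cells could move in the same way, so the source stays open. A difference by region or culture protocol stays open too and was not tested.

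Slc9a3, Prap1, Clca3 and Cdhr2, which are known from intestinal epithelium, were higher in antrum than in corpus. Scaling is argued against by the size of the changes. Rescaling moved the median log2 fold change of all genes from 0.21 to 0.006, while these genes had log2 fold changes of 3.10 to 4.34. The 12 of 12 named genes higher in antrum kept their calls after rescaling. They were chosen for large changes, so that outcome adds little. Duodenal epithelium carried into pyloric cultures predicts that intestinal list members rise together, and 0 of 7 tested ones were higher and 2, Apoa1 and Reg3g, were lower. Both stayed lower after rescaling, where Reg3g lost its call with a larger spread (log2 fold change -1.69, SE 0.31, adjusted p = 0.0782, against -1.53, SE 0.27). Adjusted over the list alone 3 were higher and 3 lower. The list holds the symbol Clca1 and not Clca3, and Slc9a3, Prap1 and Cdhr2 are not on it either. The rise of these genes is therefore not counted in it. Nor is the fall of Anpep, an aminopeptidase gene also active in intestinal epithelium, at 6.01 against 48.1 CPM in antrum and corpus (-2.83, SE 0.31, limma adjusted p = 0.00466). Yet the intestinal regulator Cdx2 was listed at 0 in corpus and forestomach and had about 15 and 30 reads (0.39 and 0.64 CPM) in the antrum libraries. A small share of duodenal cells and a regional programme of antral cells therefore cannot be told apart here. Cdx2 points to the former and the tested members of the list do not.

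The nuclear RNAs Malat1, Neat1 and Xist were higher in the glandular cultures, with Malat1 at 2898 ± 523 CPM (SD, n = 4) against 320.1 ± 93.8 CPM (SD, n = 2). Rescaling moved the median log2 fold change of all genes only from -0.13 to 0.02, and all 3 kept their calls with a smallest log2 fold change of 2.36. Changes of that size argue against the authors' scaling. A larger share of nuclear RNA would raise other nuclear RNAs by about the change of Xist, 2.20, but 7SK, U1, U2, U4, U6 and Tug1 had a median of 0.28 (SD 0.56). That median is a weak gauge of this share, since U2 and U4 differed widely within a region. In corpus 1 and corpus 2 U2 stood at 408 and 1473 CPM and U4 at 1120 and 3054 CPM. 7SK and Tug1, closer together in that pair, had log2 fold changes of -0.07 (SE 0.33) and 0.29 (SE 0.27). A difference of region or culture protocol stays open and was not tested.

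The spliceosomal RNA U2 stood at 2288, 1473 and 1673 CPM in the libraries numbered 2 of forestomach, corpus and antrum, and at 717, 408 and 397 CPM in those numbered 1.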
